A study of Arabidopsis thaliana with 8 samples.

How the data were processed

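Expression was measured on Affymetrix-type probe set arrays in shoot apices of 9-day-old Arabidopsis thaliana seedlings. The table held 8 arrays, 4 from 35S::LFY-GR plants (called LFYGR) and 4 from Landsberg erecta wild type (called WT). 35S::LFY-GR plants carry the flowering regulator LEAFY fused to the hormone-binding part of the glucocorticoid receptor, a fusion that acts in the nucleus once dexamethasone is given. Per the labels' protocols, plants of both groups received 10 µM dexamethasone in 0.1% ethanol for 4 h, and each array took RNA from a separate pool of apices. Seeds had been chilled for 7 days, and plants grew at 23 °C in continuous light or 16 h days. The labels do not say which light regime each array had. Arrays without dexamethasone were not analysed here, and the labels used here give no genetic background for 35S::LFY-GR. The comparison therefore holds the effect of the transgene together with any difference between the 2 plant lines. The labels used here name no batch, so any difference in how the 2 groups were handled cannot be told apart from these.

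The deposited values were log2 signals, 1 per probe set and array. Per the labels' protocols, RNA was amplified and biotin-labelled with NuGEN Ovation kits. The submitters' processing notes name GCRMA, MAS5 and limma, with no versions. Which of these made the deposited log2 values is not given in the sources used here. The array medians lay between 4.93 and 5.02 and the upper quartiles between 7.73 and 7.83, so no further scaling was applied. The lower quartiles lay between 2.02 and 2.15. Values in that lowest range come from dim probe sets, where background correction sets much of the value and the size of a change is least certain. The number of arrays limits the precision of every value.

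Of 22810 probe sets, 64 controls were left out and 22746 were tested. An older platform annotation named 13513 of these by 1 gene, 503 by several genes and 8730 by none. Symbols were updated through the TAIR10.1 gene table, in which 13436 of the 13513 matched, and the other 77 kept the symbol of the annotation. Unnamed probe sets were tested but are given by identifier only. LFY, AP1 and FLS2 had been chosen for separate report, LFY as a check of the labels. None of these genes had a probe set named here, so that check could not be run and they are not analysed here. No genome build is stated with the values, so no coordinates are given.

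The groups were compared as LFYGR minus WT with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate). P-values were adjusted by the Benjamini-Hochberg method over all 22746 probe sets, and a probe set was called changed at an adjusted p under 0.05. Errors of log2 differences are limma's moderated standard errors (SE), and errors of group means are standard deviations (SD) over 4 arrays. Single values outside the fit were compared with an exact two-sided permutation test, whose smallest possible p with 4 against 4 arrays is 0.0286.

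The 19 gene lists, the rule for named genes, the tests and the alternatives were set before the data were examined, except where stated. Named genes were the 8 largest rises and the 8 largest falls among called probe sets that name 1 gene and whose LFYGR and WT arrays did not overlap. To these were added, from each list, up to 4 called members of largest change, or up to 2 members of smallest p where none was called. A list member was represented by its probe set of highest mean. Of 360 genes in the lists, 47 had a probe set named here. The 7 lists with at least 3 measured members were tested with camera at its preset correlation of 0.01 and adjusted over those 7. An estimated correlation and fry were run as alternatives.

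Other alternatives were an intensity trend, a robust prior, a filter keeping probe sets above log2 5 on at least 4 arrays, quantile normalization, median centring, and log2 after adding 16. The replicate number as a block, each array left out in turn, a 2-fold minimum, an adjusted p under 0.01 and all probe sets of list members were also run. A covariate for the 3' minus 5' signal of the actin, GAPDH and ubiquitin controls was added after the data were seen. The procedure was tested on simulated data for LFYGR against WT over 22746 probe sets, with 200 changed in each of 5 simulations. It recovered 49.6% of changes of log2 0.5, 92.2% of log2 1 and 100% of log2 2, with a mean false share of 4.91%. The data gave 3228 calls, far more than were planted, and the simulated noise was normal and independent between probe sets. These percentages therefore need not hold for the data. In further simulated data, camera called 20 of 20 lists shifted by log2 1 and 0 of 40 unshifted lists. Probe sets were drawn independently there, so this does not show how camera's preset correlation behaves where members of a list are correlated.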

Results

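The comparison asked which transcripts differed in seedling apices 4 h after dexamethasone was given to plants carrying the LEAFY fusion protein and to wild type. It rested on 4 LFYGR and 4 WT arrays, each from its own pool of apices. Array medians were 4.94 to 5.01 on the log2 scale in LFYGR and 4.93 to 5.02 in WT. Mean correlations across probe sets between an array and the others of its group were 0.995 to 0.997 over both groups, and each array correlated less with the other group, at 0.989 to 0.991.

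The 8 strongest falls among named genes in LFYGR included a defensin gene, a protease gene and 3 peroxidase genes. LCR67, a plant defensin, had a mean log2 signal of 3.06 ± 1.10 (SD, n = 4) in LFYGR and 9.05 ± 0.11 in WT, a 63.8-fold lower level (log2 difference -6.00 ± 0.40 SE, limma adjusted p = 9.92e-07). ATSBT5.2, a subtilisin-like protease, changed by -4.61 ± 0.19, and AT2G43590, of the chitinase family, by -4.31 ± 0.17. Peroxidase genes fell as well, with log2 differences of -3.94 ± 0.13 for AT4G11290, -3.47 ± 0.24 for Prx37 and -3.22 ± 0.18 for AT4G08780. ATC, a relative of the flowering repressor TFL1, went from 9.28 ± 0.15 in WT to 5.48 ± 0.42 in LFYGR, a 13.9-fold lower level. AT3G26960, of the pollen Ole e 1 protein family, changed by -3.58 ± 0.15. The limma adjusted p of these 8 genes lay between 6.96e-09 and 1.2e-06. The LFYGR means of LCR67, ATSBT5.2, AT3G26960 and AT4G08780, from 2.66 to 3.15, lay near the dim end of the arrays, so the sizes of these folds are uncertain. With 16 added before taking logs, which damps dim values, the differences of these 4 genes were -4.43, -2.92, -2.29 and -1.95, and those of AT2G43590 and AT4G11290 were -3.68 and -3.06. Prx37 and AT4G08780 are neighbouring, related peroxidase genes, and cross-hybridisation between their probe sets was not excluded.

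The largest rise among named genes was that of AT5G60630, from 3.60 ± 0.21 in WT to 7.30 ± 0.14 in LFYGR, a 13.0-fold higher level (log2 difference 3.70 ± 0.11 SE, limma adjusted p = 5.29e-09). AT2G26390, of the serpin protease inhibitor family, rose by 3.04 ± 0.15, and its WT mean of 2.39 lay near the dim end of the arrays. AT5G22390 rose by 3.01 ± 0.18 and AT5G42760, of a methyltransferase family, by 2.99 ± 0.11. AT5G10970, a C2H2 zinc finger gene, rose by 2.50 ± 0.09. AT3G20180, of a heavy-metal transport family, rose by 2.43 ± 0.18. AT5G03230 rose by 2.39 ± 0.12, from 7.04 ± 0.20 in WT to 9.43 ± 0.16 in LFYGR. AT2G47560, a RING-type ubiquitin ligase gene, rose by 2.37 ± 0.12. The limma adjusted p of these 8 genes lay between 5.29e-09 and 2.22e-06. With 16 added, the differences of AT5G60630, AT2G26390, AT5G22390, AT3G20180 and AT2G47560 were 2.62, 1.48, 2.35, 1.76 and 1.78. All 16 genes were called with the same direction under each of the 16 alternatives applied to single genes. Since they were chosen for the largest changes on these same arrays, this was likely in advance.

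**Figure D1:**
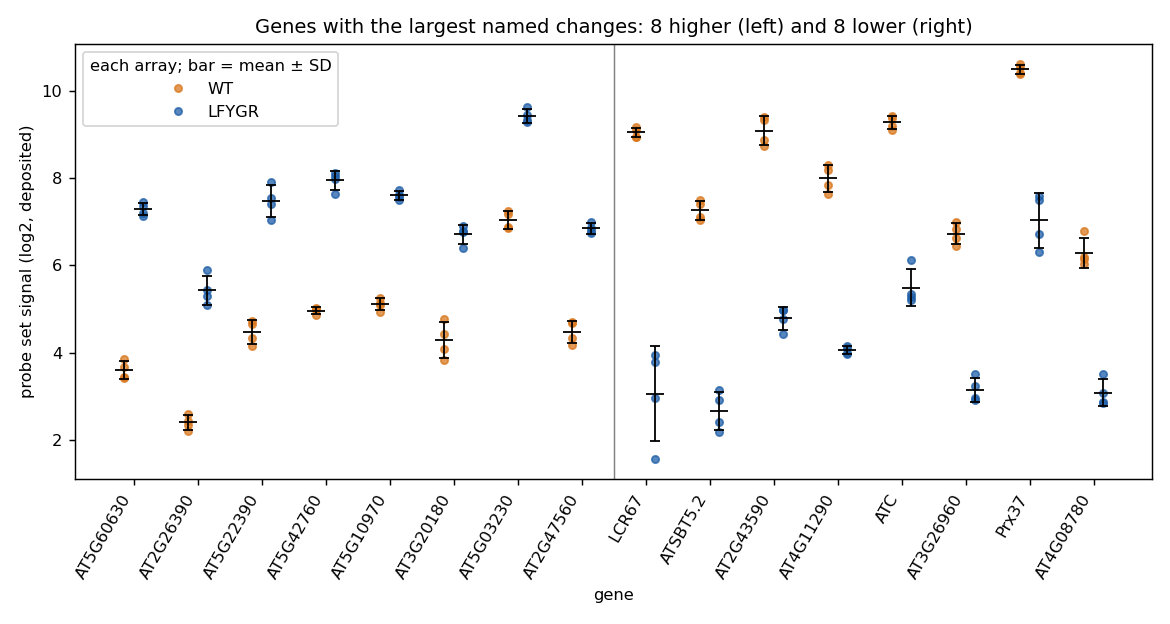
Deposited log2 signal (vertical axis) of the 16 named genes with the strongest changes, each point 1 array, orange for WT and blue for LFYGR, with bars at the mean ± SD of 4 arrays. The genes were chosen only from those whose LFYGR and WT arrays did not overlap. LCR67 had the widest LFYGR spread (SD 1.10).

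Over all probe sets, 3228 of 22746 (14.2%) were called changed, 1360 higher and 1868 lower in LFYGR. Of 602 called probe sets with at least a 2-fold change, 129 were higher and 473 (78.6%) lower. At 4-fold or more there were 30 higher and 87 lower. In 2972 of the called probe sets the LFYGR and WT arrays did not overlap. Over all tested probe sets 18.5% had no overlap, where chance alone gives 2.86%. Genes with a single name made up 1691 of the called probe sets, 754 higher and 937 lower. Unnamed probe sets were called more often (17.2%) than those named by 1 gene (12.5%), and of the 20 largest changes 10 were named. The unnamed probe set 247490_at had the largest change of all, 9.93 ± 0.15 in LFYGR against 3.22 ± 0.37 in WT, a 105-fold higher level (limma adjusted p = 1.1e-09). The WT mean lay near the dim end, so the size of this fold is uncertain, and with 16 added it was 39.0-fold. Since LFY had no probe set named here, whether 247490_at measures the transgene itself was not tested. Another unnamed probe set, 247888_at, rose by 3.79 on the log2 scale, while 258277_at was 17.1-fold lower and 266965_at fell by 3.75 on the log2 scale. With 16 added the log2 differences of these 3 were 2.37, -3.63 and -2.55. Without LFYGR replicate 2 the count of higher probe sets was 905.

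**Figure D2:**
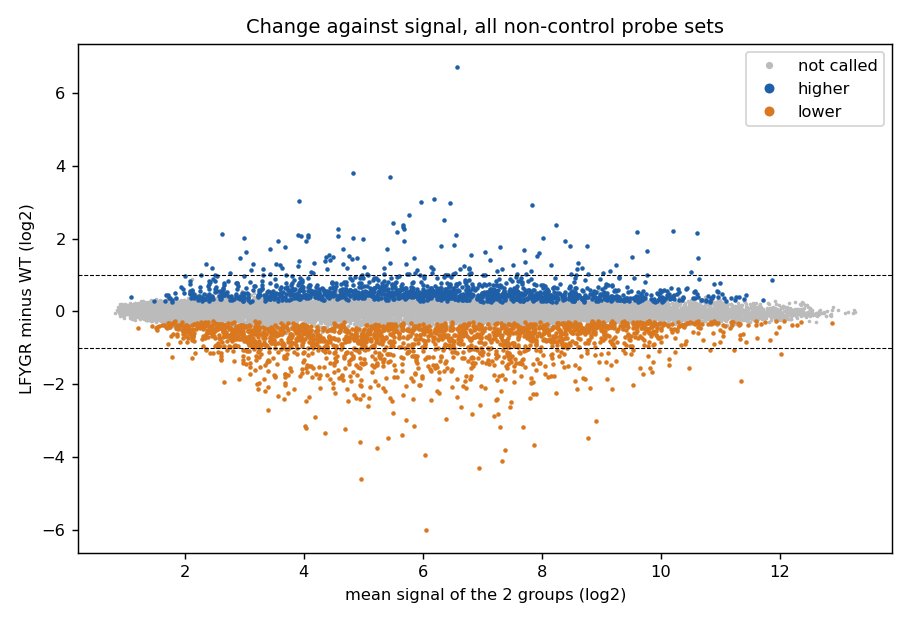
LFYGR minus WT difference (log2, vertical axis) against the mean signal of both groups (log2, horizontal axis) for 22746 probe sets, with called rises in blue, called falls in orange, others in grey and dashed lines at 2-fold. Below the lower dashed line lie 473 called probe sets and above the upper one 129.

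Of 29 listed genes of auxin response, transport and synthesis 7 were measured, of which 4 fell, 0 rose and 3 did not pass the test. The count adjusted over the list alone was also 4. GH3.3 and WES1 (GH3.5), which encode enzymes that conjugate auxin to amino acids, fell from 10.4 ± 0.23 to 9.17 ± 0.34 and from 5.43 ± 0.26 to 4.55 ± 0.16, with log2 differences of -1.22 ± 0.16 and -0.89 ± 0.13. IAA29 and IAA30, of the Aux/IAA repressor family, changed by -0.64 ± 0.13 and -0.53 ± 0.11, both at means under 2.73 in each group, near the dim end of the arrays. The limma adjusted p of these 4 genes lay between 0.000301 and 0.00672. The mean change of the list was -0.53, with a camera adjusted p = 0.00088, and the adjusted p = 0.155 with an estimated correlation. With 16 added WES1 differed by -0.59 and IAA30 by -0.14. IAA29 lost its call after 16 was added before taking logs (log2 difference -0.14, adjusted p = 0.0614, against 0.00189 to 0.0614 over its alternatives).

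Of 17 listed regulators and markers of epidermal cells 4 were measured, and 3 of these were lower, by the whole-array adjustment and adjusted over the list alone. TRY, a repressor of trichome formation, fell from 6.13 ± 0.18 to 5.45 ± 0.20 (log2 difference -0.69 ± 0.12 SE, limma adjusted p = 0.00199). SPCH and MUTE, which act in the stomatal lineage, changed by -0.48 ± 0.12 and -0.33 ± 0.08 (limma adjusted p = 0.0209 and 0.0196), while FMA, a later gene of that lineage, differed by 0.05 ± 0.12 and was not called. TRY and SPCH are neighbours in the gene table, and MUTE was dim, at 2.41 and 2.74. The mean change of the list was -0.36, with a camera adjusted p = 0.0352, and the adjusted p = 0.186 with an estimated correlation. The list was not called without LFYGR replicate 3 (adjusted p = 0.0766), without WT replicate 2 (0.0585) or with the 3' minus 5' covariate (0.0619), over a range of 0.0233 to 0.186 among the alternatives run with camera. The adjusted p was 0.00434 by fry, which tests a list against no change and not against other genes. Under the 3 settings without a call the mean change of the list was -0.31, -0.35 and -0.37, close to the -0.36 over all arrays. SPCH lost its call without LFYGR replicate 1 (0.0606) or 3 (0.0623), without WT replicate 2 (0.0562) or 3 (0.0663) and with 16 added (0.057), and MUTE without LFYGR replicate 2 (0.0653) or 3 (0.0587). Without these arrays SPCH differed by -0.45 to -0.40 and MUTE by -0.30 and -0.31, and with 16 added SPCH differed by -0.24 and MUTE by -0.09. The lowest adjusted p among the alternatives was 0.00756 for SPCH and 0.00546 for MUTE.

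The 2 measured genes of 28 in the jasmonate list fell, also when adjusted over the list alone. PDF1.2, a defensin gene, went from 9.77 ± 0.14 to 8.38 ± 0.29, and THI2.1, a thionin gene, from 4.28 ± 0.08 to 3.05 ± 0.32 (log2 differences -1.39 ± 0.14 and -1.23 ± 0.14 SE, limma adjusted p = 2.1e-05 and 6.35e-05). THI2.1 was dim in LFYGR, and with 16 added its difference was -0.54. In the list of pattern-triggered immunity genes 7 of 30 were measured and 1 was called, and the count adjusted over the list alone was also 1. This gene was PUB23, a ubiquitin ligase gene that restrains immune responses, which rose by 0.42 ± 0.10 (limma adjusted p = 0.0107), or by 0.23 with 16 added. EFR, BIK1, WRKY22, WRKY53, PUB22 and PUB24 were not called, with differences from -0.07 to 0.25. Of these, EFR, at 1.92 and 1.78, and PUB24, at 2.76 and 2.82, were dim. The camera adjusted p of that list was 0.385, and the adjusted p = 0.432 with an estimated correlation. SAG101, the 1 measured gene of 19 in the salicylic acid list, differed by -0.08 ± 0.09, and BCAT4, the 1 of 19 in the glucosinolate and camalexin list, by 0.12 ± 0.09. Neither passed the test over all probe sets or adjusted over the list alone.

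Of the measured genes of flowering and of the shoot meristem, FD was higher and UFO, JAG and PTL were lower. FD, which encodes a bZIP partner of the flowering signal FT, rose from 3.65 ± 0.13 to 4.32 ± 0.44 (log2 difference 0.67 ± 0.18 SE, limma adjusted p = 0.0263). It was the only called gene of 5 measured among 22 flowering-time genes, also adjusted over the list alone; AGL24, GI, AGL42 and SMZ were not called, and the list's camera adjusted p was 0.385. AGL42 was dim, at 2.86 and 2.62. UFO, an F-box gene of floral meristems, changed by -0.41 ± 0.10 (limma adjusted p = 0.0171) at dim levels of 2.19 and 2.61. SPL differed by 0.03 ± 0.09 at still dimmer levels of 1.66 and 1.63. UFO and SPL were the 2 measured of 21 floral identity genes, 1 of them past the test adjusted over the list alone. Among 6 measured of 32 genes of the meristem, organ boundaries and polarity, JAG and PTL changed by -0.50 ± 0.12 and -0.44 ± 0.13 (limma adjusted p = 0.012 and 0.0477). JAG was dim, at 2.15 and 2.66. With 16 added UFO differed by -0.10 and JAG by -0.13. CLV3, at dim levels of 1.59 and 1.69, and LAS, at 2.19 and 2.18, were not called over all probe sets. YAB3 and PHV were not called either. When adjusted over the list alone 3 genes passed, YAB3 among them. That list had a camera adjusted p = 0.0923, the adjusted p = 0.217 with an estimated correlation, and an adjusted p = 0.0135 by fry. None of the 10 listed targets of LEAFY from earlier work had a probe set named here.

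With 7 arrays in place of 8, some of these calls were lost while the differences stayed of similar size. FD lost its call without LFYGR replicate 2 (adjusted p = 0.0607), without WT replicate 2 (0.0519), 3 (0.0767) or 4 (0.0697) and with 16 added (0.113), over a range from 0.00138. Its log2 difference was 0.63 to 0.68 without those arrays and 0.34 with 16 added. UFO lost its call without LFYGR replicate 3 (0.0516) or without WT replicate 1 (0.0521) or 3 (0.0569), over a range from 0.0111, with a log2 difference of -0.39 to -0.35 without them. PTL lost its call in 8 of 16 alternatives, without LFYGR replicate 1 (0.116) or 2 (0.132), without WT replicate 1 (0.101), 2 (0.115) or 4 (0.114), with an intensity trend (0.053), with 16 added (0.0938) and with the replicate block (0.073), over a range from 0.0188. Its log2 difference was -0.43 to -0.33 without those arrays and -0.35 with 16 added.

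Hormone receptors and response regulators gave single calls. GID1B, a gibberellin receptor gene, rose from 5.92 ± 0.35 to 6.68 ± 0.20 (log2 difference 0.77 ± 0.16 SE, limma adjusted p = 0.00647), while GID1A and GID1C differed by -0.26 ± 0.12 and -0.17 ± 0.11 and were not called. These were 3 of 24 gibberellin genes, 1 past the test adjusted over the list alone. The list's mean was 0.11 and its median -0.17, with a camera adjusted p = 0.988. RR16, a cytokinin response regulator gene, changed by -0.76 ± 0.19 (limma adjusted p = 0.0179), and ARR15 differed by -0.01 ± 0.17. These were 2 of 24 cytokinin genes, 1 past the test adjusted over the list alone. RR16 lost its call without WT replicate 3 (adjusted p = 0.0563) and with 16 added (0.0692), over a range from 0.00258, with log2 differences of -0.63 and -0.53.

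Apart from the epidermal list, genes chosen as checks of tissue makeup and handling were not called over all probe sets. LHCB4.1, RCA and PRK, 3 of 20 photosynthesis genes, differed by -0.08, 0.09 and 0.03. That list had a mean of 0.01 and a camera adjusted p = 0.988, with camera's direction downward, opposite in sign to the mean, and 0 members passed when adjusted over the list alone. AUR1, a mitotic kinase gene and the 1 measured of 17 cell cycle genes, differed by 0.34 ± 0.11 (limma adjusted p = 0.0645), and passed with an intensity trend (0.0289), with quantile normalization (0.043) and without WT replicate 2 (0.0104), over a range up to 0.166. EXPA7, 1 of 14 root markers, differed by 0.21 ± 0.09 at levels of 1.82 and 1.60, and GI, 1 of 14 clock genes, by 0.27 ± 0.10. AUR1, EXPA7 and GI passed when adjusted over the list alone, where each was the single gene tested. ATHSP22.0, 1 of 9 heat shock genes, differed by -0.03 ± 0.09 at dim levels of 1.46 and 1.48, where a change could be missed. STZ, 1 of 13 genes of touch, wounding and cold, differed by 0.42 ± 0.19, and was called without LFYGR replicate 2 (limma adjusted p = 0.0484, over a range up to 0.432). Neither ATHSP22.0 nor STZ passed when adjusted over the list alone. None of the 10 vascular genes was measured.

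**Figure D3:**
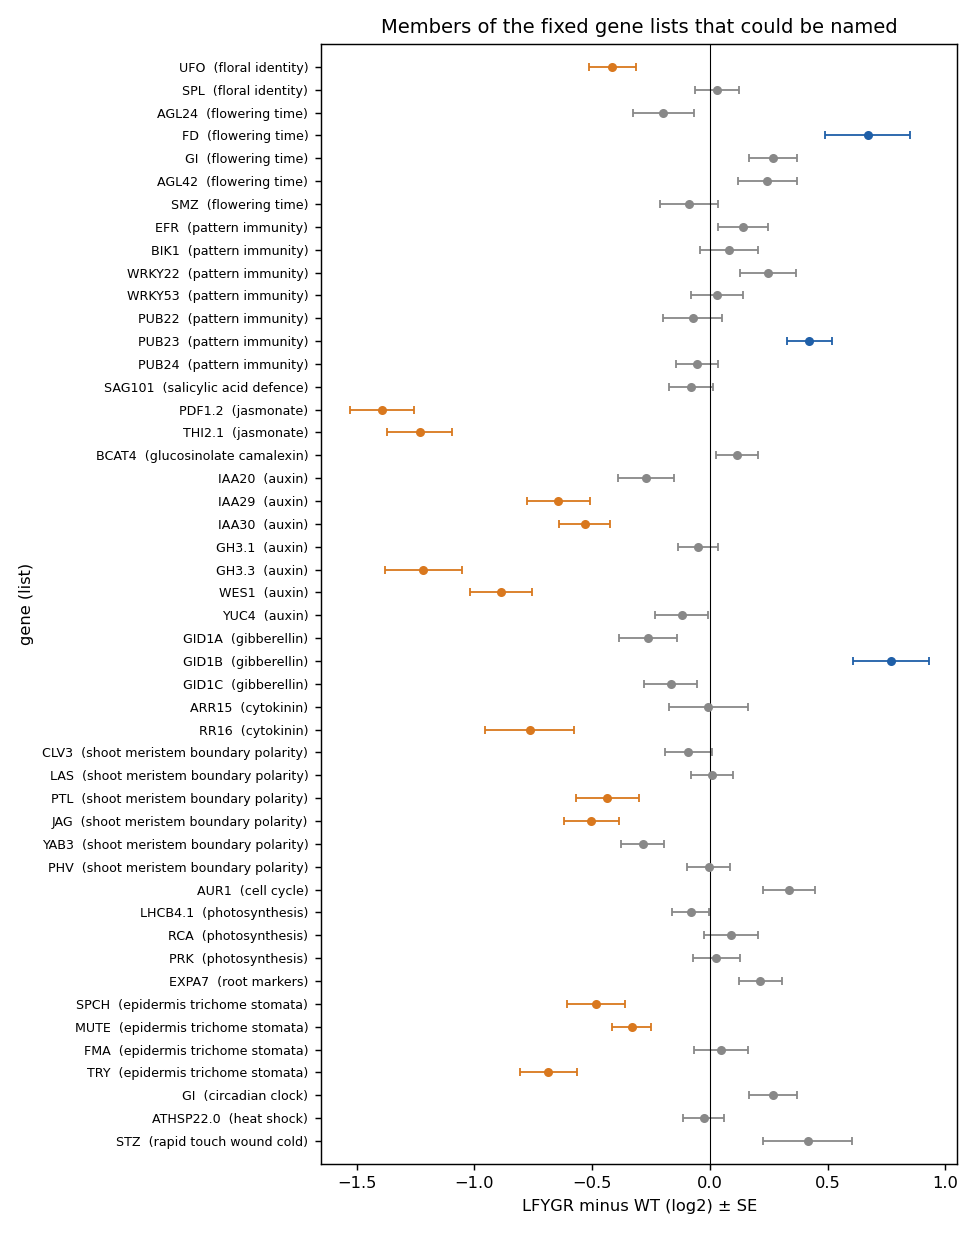
LFYGR minus WT difference (log2 ± SE, horizontal axis) of each measured gene of the fixed lists (vertical axis), with called rises in blue, called falls in orange and genes that did not pass the test in grey. Of 47 distinct genes, 13 were lower and 3 higher, and GI stands in 2 lists.

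The 25S rRNA control was 6.33 ± 0.22 in LFYGR and 5.35 ± 0.43 in WT (n = 4 each, exact two-sided permutation p = 0.0286, the smallest possible). It was 1 of 2 among 64 control probe sets whose groups did not overlap, where chance gives about 1.83, and the 5S rRNA control differed by -0.08 with overlapping arrays. That chance count is rough, since several controls measure the same transcript, and it takes no account of size. The 25S control differed by 0.98, the other separated control, CreX-5, by -0.17, and the largest difference of the remaining controls was -0.33. LFYGR replicate 4 had a mean 3' minus 5' signal of 3.43 over the actin, GAPDH and ubiquitin controls, where the highest of the other 7 arrays had 3.13. The group difference in that signal was 0.12 (exact two-sided permutation p = 0.257).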

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

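The test of 5' signal on LFYGR replicate 4 was chosen after the values of that array had been seen, and the test of its response was chosen before its result was seen. Sample values were compared within each group of 4 arrays by the gap of the most extreme array to its nearest neighbour. Of 90 such groups 6 had an array far from the others, where chance gives about 4.5.

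LFYGR replicate 4 had a mean correlation of 0.995 with its own group, where the other LFYGR arrays had 0.997. The 3' minus 5' signal of its control transcripts exceeded the highest of the other 7 arrays by 0.303, against an SD of 0.0496 among those 7, which is consistent with RNA or amplification of lower quality. A smaller response, from wild-type material or weaker induction, also had the values it needs. The slope of this array's difference from WT on that of the other LFYGR arrays was 0.880, where the slopes of the other 3 LFYGR arrays lay between 0.949 and 1.02. Both explanations stay open, and no biological explanation was tested.

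For 4 named genes, 1 array lay far from the rest of its group. ATC read 6.11 on LFYGR replicate 3, where the other LFYGR arrays ranged from 5.20 to 5.34 and the WT mean was 9.28. STZ read 4.91 on LFYGR replicate 2, against 5.55 to 5.64 on the others. BCAT4 read 12.7 on LFYGR replicate 4, against 13.00 to 13.04, and RCA read 9.18 on that array, against 9.56 to 9.58. WT replicate 2 had a mean correlation of 0.997138 with its own group, just under the 0.99736 to 0.997398 of the others. The 25S rRNA control, which entered no gene comparison, was higher in LFYGR by 0.98 on the log2 scale (exact two-sided permutation p = 0.0286, with 4 arrays per group). Chance gives about 1.83 separations of any size among 64 control probe sets, and 2 were seen. The other, CreX-5, differed by only -0.17.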

How the results depend on the processing

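The 3' minus 5' covariate was chosen after the data were seen. The count of changed probe sets was 3295 with an intensity trend, 3202 with a robust prior, 2362 of 11477 tested with the filter on dim probe sets, 3379 after quantile normalization, 3223 after median centring, 2811 with 16 added and 3224 with the covariate, and 2481 to 3476 with 1 array left out. With 1 array left out, the count of higher probe sets ranged from 905, without LFYGR replicate 2, to 1553, without LFYGR replicate 4, and it was 1559 after quantile normalization. Stricter thresholds gave fewer by construction: 602 changed, 129 higher and 473 lower at 2-fold or more, and 1875 changed and 595 higher at an adjusted p under 0.01. The count of shifted lists, 2, became 0 with the filter on dim probe sets, which left under 3 members of both lists. It was 1 with the covariate, 0 with an estimated correlation and 1 to 2 with 1 array left out, being 1 without LFYGR replicate 3 or WT replicate 2, and the cause was not tested. By fry, which tests each list against no change, it was 3, the meristem list added. The mean of the photosynthesis list, which was not called, changed sign with single arrays left out (-0.0258 to 0.0795), as did ATHSP22.0 (-0.0594 to 0.0388), and the cause was not tested. Among values of named genes under the alternatives, 614 kept direction and side of the threshold, 26 lost a call, 4 gained one and 1 changed sign. The filter on dim probe sets removed the called genes UFO, JAG, IAA29, IAA30, MUTE, FD, SPCH, PUB23 and THI2.1, whose values are limited by low signal.

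The replicate block gave 3191 changed probe sets, of which 2907 were also called without it. Deviations of same-numbered arrays from their group means correlated at 0.086, 0.028, 0.019 and 0.052. All were positive but lay within the range of differently numbered arrays, -0.098 to 0.088. Whether the numbers pair the samples stays open. Among named genes the block changed the call of PTL alone, and no list call.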

Other observations

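The gene families below were chosen after the data were seen, as were their tests; the tests of the share of falls, of splits of the arrays and of chromosome position were set before their results were seen. Of 10 measured expansins (EXPA), proteins that loosen cell walls, 3 fell and 0 rose in LFYGR. EXPA15 went from 5.79 ± 0.14 (SD, n = 4) to 3.67 ± 0.05, EXPA4 changed by -1.28 ± 0.10 (SE) and EXPA9 by -0.63 ± 0.11. EXPA4 and EXPA9 were near the dim end in LFYGR, at 2.84 and 2.15, as was XTH19, at 2.27. Among 10 xyloglucan endotransglucosylase/hydrolases (XTH) 3 fell and 1 rose: XTH18 changed by -1.27 ± 0.11 and XTH19 by -0.96 ± 0.11, while EXGT-A3 rose by 0.34 ± 0.10 (limma adjusted p = 0.0499). No XTH gene was called higher when any 1 of LFYGR replicates 1, 2 and 3 or WT replicates 2, 3 and 4 was left out. Of 12 defensin-like peptides (LCR and PDF) 4 fell and 0 rose. Beside LCR67 and PDF1.2 these were LCR68, changed by -0.84 ± 0.09, and LCR69, changed by -0.31 ± 0.08 at a high level of 13.0 in WT. Without LFYGR replicate 2 or 3 or WT replicate 4 the count of this family was 3. The mean log2 difference was -0.77 for the defensin-like peptides and -0.42 for the expansins, but the medians were only -0.21 and -0.12. LCR67, at -6.00, weighs heavily in the mean of the defensin-like peptides.

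Of 15 IQD genes, which encode calmodulin-binding scaffold proteins, 5 fell and 2 rose. IQD26 fell from 7.53 ± 0.03 to 6.11 ± 0.11, IQD33 changed by -1.24 ± 0.15 and IQD23 by -0.62 ± 0.11. The count of IQD rises was 1 without any 1 of LFYGR replicates 1, 2 and 3 or WT replicates 1, 2 and 4. Of 14 TRM genes (TON1 recruiting motif) 4 fell and 1 rose, with TRM25 changed by -0.81 ± 0.13 and TRM19 by -0.70 ± 0.09. IQD23 and TRM25 were dim in LFYGR, at 2.95 and 2.38. Beta-glucosidases (BGLU) went both ways, 7 of 22 lower and 1 higher: BGLU44 changed by -1.47 ± 0.09 and BGLU15 by 1.55 ± 0.11. Over 29 families the camera adjusted p was 0.00344 for the defensin-like peptides, 0.0243 for expansins, 0.0243 for IQD, 0.0316 for TRM, 0.0521 for XTH and 0.0521 for BGLU, each in the direction of lower levels. It was 0.0507 in the direction of higher levels for the vacuolar protein sorting genes (VPS), of which 2 of 14 had a difference below 0 and 1 was called, VPS24.1, which rose by 0.54 ± 0.11. With an estimated correlation the adjusted p = 0.263 for VPS and 0.239 for each of the other 6 families. The TRM shift was not called without WT replicate 3 (adjusted p = 0.062) or with 16 added (0.0524), over a range from 0.0223 to 0.239. Its mean was -0.27 over all arrays, -0.25 without WT replicate 3 and -0.14 with 16 added. XTH was called after quantile normalization (0.049) and median centring (0.0499) and without LFYGR replicate 3 (0.0499) or WT replicate 2 (0.0417), over a range up to 0.239. BGLU was called after quantile normalization (0.0401), with the covariate (0.0364) and without LFYGR replicate 4 (0.036) or WT replicate 1 (0.0458) or 2 (0.0417), over a range up to 0.239. VPS was called after quantile normalization (0.0368) and median centring (0.0455), with the replicate block (0.0491), with the covariate (0.0364) and without LFYGR replicate 4 (0.0344) or WT replicate 2 (0.0327) or 4 (0.0358), over a range up to 0.263. The count of VPS rises was 3 without WT replicate 2 and 2 without WT replicate 4. No TRM gene was called higher without any 1 of LFYGR replicates 1 and 2 or the WT replicates.

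Genes of the plastid genome gave a shift that followed 1 array. Of 69 plastid genes 59 had a difference below 0, 2 were called lower (psaC by -0.47 and psbN by -0.47) and 1 higher (ndhJ by 0.53), with a mean of -0.15 and a camera adjusted p = 0.00344, and the adjusted p = 0.747 with an estimated correlation. Without LFYGR replicate 4 the mean was -0.03 (camera adjusted p = 0.344), and with the 3' minus 5' covariate it was 0.01 (0.903), over a range from 4.34e-06 to 0.903 among the alternatives. With 1 array left out, 0 to 3 plastid genes were called lower and 0 to 2 higher.

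Falls of 2-fold or more outnumbered rises, 473 against 129. A difference of scale left in the deposited values does not account for this. The share lower was 78.0% after quantile normalization and 78.4% after median centring. The array medians and upper quartiles were already close, so both steps changed little. A difference between arrays removed before deposit could not be seen this way. Values near background do not account for the excess of falls either. Of 175 called probe sets of 2-fold or more with a mean of log2 7 or more, 138 (78.9%) were lower. Without LFYGR replicate 4, the array of weaker 5' signal, the share was 78.4%. The induced fusion protein, other differences between the 2 plant lines and any difference in how the groups were handled stay open and untested.

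The number of called probe sets was compared between the real groups and other splits of the 8 arrays into equal groups. Of 35 splits of the arrays 1, the real one, gave as many as 3228, and the highest of the other splits gave 0. Being the highest of 35 is the strongest result this test can give, so chance is not excluded. Every other split mixes LFYGR and WT arrays, which widens the spread within its groups. Few calls were therefore likely there, whatever separates the LFYGR from the WT arrays.

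The position of called genes along the chromosomes was compared with shuffles to ask whether a linked segment of another genotype around the transgene could have given the calls. The highest count of called genes in any 30 neighbouring measured genes was 11. The median of 1000 shuffles was also 11 and their 95th percentile 13, so no dense segment was found among the 13217 genes placed. Only a segment with more than 13 of 30 genes called would have stood out, and unnamed probe sets were not placed. The background of 35S::LFY-GR is not given in the labels. Scattered differences of genotype, or a segment with fewer calls, therefore stay open. Adjacent measured genes were called in the same direction in 168 pairs, where the shuffles had a mean of 106 (one-sided permutation p = 0.000999, the smallest they can give). Called genes include neighbouring related ones, such as the peroxidase genes Prx37 and AT4G08780, and the cause of this excess was not tested.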
